A study of Kluyveromyces lactis with 12 samples.

How the data were processed

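RNA of Kluyveromyces lactis, a budding yeast, was measured on 12 two-colour Agilent arrays. Each array carried RNA of a Klyap8 deletion strain in one dye and RNA of the wild type from the same condition in the other. Per the labels, cells were left untreated, exposed to sodium arsenite or exposed to tert-butyl hydroperoxide (t-BOOH) for 30 min, with 4 biological experiments per condition. The labels give 0.25 mM for t-BOOH and conflict on arsenite, with 25 mM in the treatment labels and 0.1 mM in the treatment protocol. The dye orientation, taken from the strain and dye labels, was swapped on 2 of the 4 arrays of each condition. Untreated and arsenite arrays lay on slide 1 and t-BOOH arrays on slide 2, so for any comparison of t-BOOH with another condition, slide and condition cannot be told apart. The deletion and the wild type shared each array.

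Per the file headers, the scans were read with Feature Extraction 10.7.3.1. Spot and local background brightness per channel are median pixel intensity values, deposited without normalization. The processed signals are intensity values that, per the file headers, were background-subtracted and dye-normalized by the scanner software, and the deposited log10 ratios were computed from them as red over green. A table of the whole series holds the authors' log2 values per array. Its scale and direction, deletion over wild type, were checked against the log2 ratios computed here from the scan of the same array. Correlations over genes were 0.991 to 0.999 and slopes 1.01 to 1.03. Its column medians were -0.01, -0.00, -0.00 and -0.01 for untreated replicates 1 to 4, -0.02, 0.00, 0.00 and 0.00 for arsenite, and 0.01, -0.01, 0.01 and -0.03 for t-BOOH. How the authors normalized and centred that table is not given in the sources used here, and neither is the genome build of the array design.

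Log2 ratios were computed from the median signals with limma 3.58.1 in R 4.3.3. The design had been written for mean signals, and the median signals were used in their place. Background was corrected by normexp with an offset of 50, and ratios were normalized by loess within each array, with control spots and outlier flags left out. The spots of a probe were averaged, and 5076 of the 5081 genes had 2 spots. Of the 5081 genes, 5069 were well above background in either channel on at least 4 arrays and were tested, and 12 were left out as dim. No spot was saturated. Gene names came from a RefSeq table of assembly ASM251v1, used for names, for which genes neighbour each other and for coding lengths. It matched 5069 identifiers and left 12 unmatched. A symbol was found for 3955 genes, and the other 1126 keep their identifier. Most symbols are those of Saccharomyces cerevisiae counterparts, so what a gene is known to do refers to that yeast. The deleted gene was taken as the gene with the symbol ARR1, another name of YAP8. No gene in the table carries the symbol YAP1, and its values are not reported here.

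Deletion against wild type was tested with limma on the 12 ratios, with a coefficient for each of the 3 conditions and 1 for the dye. All arrays shared 1 estimate of the spread, with 8 residual and 4.61 prior degrees of freedom. Differences of the ratio between conditions were contrasts of the same fit. No array hybridised treated against untreated RNA. The response of the wild type to each stress was therefore tested by limma's separate-channel analysis of the 24 channels, after Aquantile normalization between arrays, with an intraspot correlation of 0.639. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors (SE) are from the fit, and SDs are over the 4 arrays of a condition. The number of arrays limits the precision.

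The groups, tests, alternatives, gene lists and naming rule were set before the data were examined. Tests of what may explain the chromosome-end, ribosomal protein and t-BOOH replicate 3 patterns were set with the pattern known. Genes named are the 10 highest and 10 lowest called genes with the same direction on all 4 arrays. For the stress responses, the wild-type channels must not overlap. The 2 called members of each list with the largest change and the deleted gene were added, and for differences between conditions the 5 highest and 5 lowest called genes, of which 1 is not reported here. The 14 lists cover arsenic detoxification, thiol redox and peroxide removal, pentose phosphate and NADPH, sulfur assimilation, iron uptake, heat shock proteins, the proteasome and ubiquitin, ribosome biogenesis, stress carbohydrates, mitochondrial respiration, multidrug and metal efflux, mating and cell type, strain markers, and cytosolic ribosomal proteins. Members were matched by gene symbol, and those without a measured match were not tested. Measured were 5 of 9 arsenic, 6 of 13 pentose phosphate, 9 of 33 multidrug efflux and 11 of 37 stress carbohydrate members. In thiol redox 27 of 42 and in iron uptake 23 of 39 were measured. Counts and calls of a list cover its measured members only. Lists were tested with limma's cameraPR, which sets a list against all other genes. The correlation between genes was preset at 0.01 and, as an alternative, estimated from the residuals. Negative estimates were set to 0. For the arsenic list the estimate was 0 in every comparison, so for that list the alternative was looser than the preset.

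The tests were tried on simulated data with 5069 genes, of which 200 were changed. For deletion against untreated wild type, 98.5% of genes changed by 1 on the log2 scale and 58.2% of those changed by 0.5 were recovered. For the wild-type arsenite response the shares were 71.6% and 8.96%, and for the t-BOOH response 77.6% and 10.4%. For the difference between arsenite and untreated ratios they were 86.6% and 19.4%. The simulation gave all conditions the same spread.

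Alternatives were no background subtraction, the scanner's processed signals, median centring, 2 other filters on dim genes, no dye coefficient, only the arrays of the conditions compared, the replicate number as a block, a trended robust variance, the authors' log2 table, wild-type channels alone, median scaling between arrays, and each array left out in turn. A fit without 3 arrays that stood apart from their group was added later.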

Results

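The response of K. lactis to arsenite and to a peroxide, and the part of the transcription factor KlYap8 in it, was followed on 12 arrays, 4 each for untreated, arsenite-treated and t-BOOH-treated cells. Every array set the Klyap8 deletion strain against the wild type. Median spot intensity ranged from 719 (t-BOOH replicate 1) to 3048.75 (untreated replicate 3) in Cy3 and from 2373.75 to 7526 in Cy5, over background medians of at most 39. The share of genes well above background was 97.4% or more in each channel. Log2 levels over genes correlated with the other arrays of the condition at 0.994 to 0.996 for arsenite. For untreated cells the mean correlation was 0.977 to 0.978 except on replicate 4 (0.943), and for t-BOOH 0.964 to 0.966 except on replicate 1 (0.916). Log2 ratios of deletion over wild type correlated less. In untreated cells their mean correlation with the other arrays was 0.307, 0.221, 0.191 and 0.168 for replicates 1 to 4. Pairs of untreated arrays ran from -0.064 to 0.593, so these ratios were poorly reproduced. For arsenite the mean correlation was 0.444 to 0.600, and for t-BOOH 0.414 to 0.540 except on replicate 3 (0.03).

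ARR1 (KLLA0E00265g), the gene removed in the deletion strain and the counterpart of the arsenic-responsive regulator Yap8, was lower in the deletion strain on all 12 arrays. Its log2 ratios of deletion over wild type were -1.36, -1.22, -1.34 and -0.61 in untreated cells, -2.20, -2.05, -2.19 and -1.93 under arsenite, and -1.79, -1.59, -1.56 and -1.81 under t-BOOH. Means were -1.13 ± 0.35, -2.09 ± 0.13 and -1.69 ± 0.13 (SD, n = 4 each), with limma adjusted p of 1.62e-04, 9.22e-07 and 8.10e-06. The neighbouring ARR2 (KLLA0E00243g), named after the arsenate reductase, was lower by more. Its ratios were -1.65 ± 0.28 untreated, -4.40 ± 0.21 under arsenite, a 21.1-fold difference, and -1.95 ± 0.12 under t-BOOH (SD, n = 4 each, limma adjusted p = 1.85e-05, 1.08e-10 and 1.30e-06). The position of the ARR1 probe relative to the deleted part is not given in the sources used here, so the remaining ARR1 signal has no set meaning.

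**Figure D1:**
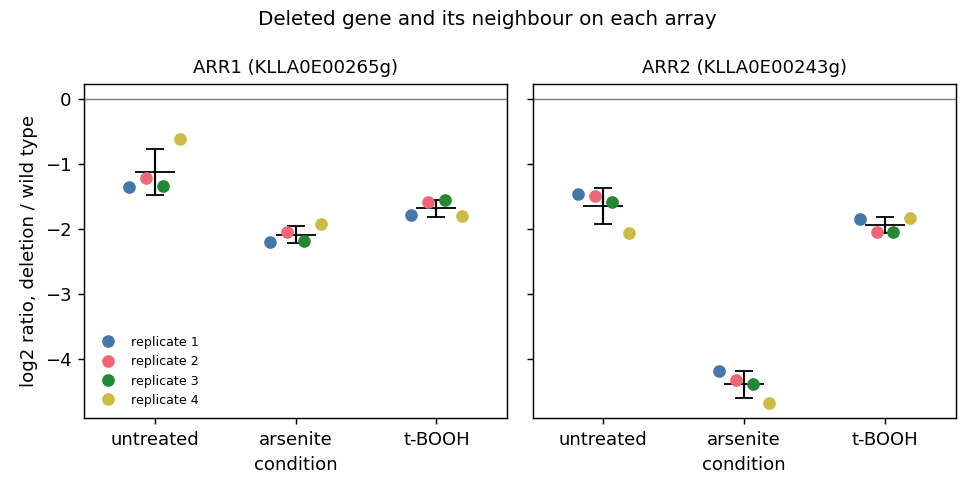
Log2 ratio of deletion over wild type for ARR1 (left) and ARR2 (right) on each of the 12 arrays, by condition. Coloured points are arrays, the black dash is the mean of 4 and the bar its SD. ARR2 lies between -4.19 and -4.68 under arsenite and at -2.06 or above in the other conditions.

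In untreated cells few genes differed between the deletion strain and the wild type. Of 5069 genes tested, 31 were called, and all 31 were lower in the deletion strain, 17 of them by at least 2-fold. The strongest were members of a set of 12 genes at chromosome ends, among them KLLA0C00110g (log2 ratio -2.34, SE 0.22), KLLA0D20031g (-2.32, SE 0.21), KLLA0F00132g, KLLA0A00110g, KLLA0E00111g, KLLA0D20009g (-2.23, SE 0.21), KLLA0A00132g, KLLA0C00132g, KLLA0B00143g and KLLA0F00154g (-2.08, SE 0.20). Of the gene lists, arsenic detoxification was lower (2 of 5 members called, also 2 adjusted over the list alone; median -0.32, adjusted p = 6.49e-11, and adjusted p = 2.46e-11 with an estimated correlation). The called members were the deleted gene ARR1 and its neighbour ARR2, here and under both stresses. ARR1 is the deleted gene, and the list was not tested without it, so the call of the list says nothing of the other members, none of which passed. Ribosome biogenesis genes had a median of 0.22, above 0 for 89 of 92 members with none called over all genes or adjusted over the list alone (adjusted p = 1.97e-06, and adjusted p = 0.815 with an estimated correlation). Without untreated replicate 3 that median was 0.01 (adjusted p = 0.959). Sulfur assimilation genes had a median of -0.14, with 0 of 31 called and 0 adjusted over the list alone (adjusted p = 3.42e-04, and adjusted p = 0.278 with an estimated correlation). The proteasome list had a median of -0.08 with 0 of 42 called and 0 adjusted over the list alone (adjusted p = 0.0447, and adjusted p = 0.815 with an estimated correlation), a call lost without untreated replicate 1 (adjusted p = 0.185), untreated replicate 3 (0.638), arsenite replicate 2 (0.0610), arsenite replicate 4 (0.0521), t-BOOH replicate 1 (0.0512) or t-BOOH replicate 2 (0.0504). The other 10 lists did not pass, ribosomal proteins included (median 0.09, adjusted p = 0.112). That list passed without untreated replicate 4 (median 0.25, adjusted p = 1.69e-04), t-BOOH replicate 1 (0.0438) or t-BOOH replicate 3 (0.0396), and mitochondrial respiration without untreated replicate 1 (-0.09, adjusted p = 0.0444). For multidrug efflux the median (0.05) differed in sign from the mean (-0.06) and the test. The count of 31 fell to 19 without untreated replicate 2 or 3 and rose to 51 without t-BOOH replicate 3, of which 6 were higher. Higher genes were also called with processed signals (2 of 40), on the untreated arrays alone (1 of 21) and without 3 arrays that stood apart (15 of 72). An unadjusted p under 0.05 was reached by 525 genes.

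Under arsenite, JLP1, STE6, KAR4 and SRX1 were among the genes lower in the deletion strain beside ARR1 and ARR2. JLP1 (KLLA0F26158g), a sulfonate dioxygenase, had a log2 ratio of -1.89 (SE 0.18, limma adjusted p = 3.15e-05), STE6, the exporter of the a-factor pheromone, -1.67 (SE 0.24), and KAR4, a regulator of mating genes, -0.82 (SE 0.11). SRX1, sulfiredoxin, stood at -0.83 (SE 0.13), a call lost without arsenite replicate 2 (value there within -0.93 to -0.71). FES1 (-1.22), ECM4 (-0.76) and SMF3 (-0.51) were called but lost without arsenite replicate 1, 2 or 3, with values no nearer to 0 than -0.98, -0.65 and -0.45 over all arrays left out. CUZ1 (-0.96), ISA2 (-0.48) and HIS3 (-0.40) were called and lost without arsenite replicate 1, 2 or 3, untreated replicate 2 or t-BOOH replicate 2 or 4, CUZ1 and HIS3 also without untreated replicate 1 and CUZ1 without untreated replicate 3 or 4. Their values came no nearer to 0 than -0.81, -0.40 and -0.33. The chromosome-end genes were lower again, from KLLA0A00132g (-2.70, SE 0.20), KLLA0D20009g and KLLA0C00132g over KLLA0B00143g, KLLA0E00133g, KLLA0D00143g and KLLA0F00154g to KLLA0D20031g and KLLA0C00110g (-2.45, SE 0.22).

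Genes higher in the deletion strain under arsenite included RPL5, RPS9B and RRP5. KLLA0F21164g had a log2 ratio of 0.98 (SE 0.19), RPL5 0.93 (SE 0.21), RPS9B 0.93 (SE 0.17), RPS6A 0.89 (SE 0.21), RPS1B 0.83 (SE 0.20) and the ribosome assembly factors RRP5 0.89 (SE 0.21) and MAK21 0.78 (SE 0.20). KLLA0E10869g (0.80), the histone gene HTB2 (0.78) and KLLA0E00573g (0.75) completed the 10 highest. Each of these 10 calls was lost without arsenite replicate 2 and, except KLLA0E00573g, without arsenite replicate 1 or 3, with values of 0.53 or more on leaving out any array. RPS6A, RPS1B, MAK21 and KLLA0E10869g were also lost without untreated replicate 1 or 2 or t-BOOH replicate 2 or 4, KLLA0E10869g without untreated replicate 3, RRP5 and HTB2 without untreated replicate 1 or t-BOOH replicate 2, and HTB2 without arsenite replicate 4. Of 56 ribosomal protein genes 7 were called higher, or 50 adjusted over the list alone, and all 56 had a ratio above 0 (median 0.67, adjusted p = 9.34e-20, and adjusted p = 0.616 with an estimated correlation). Of 92 ribosome biogenesis genes 4 were called higher, or 5 adjusted over the list alone (median 0.46, adjusted p = 8.98e-15, and adjusted p = 0.620 with an estimated correlation). Of 27 thiol redox genes 4 were lower, or 7 adjusted over the list alone (median -0.24, adjusted p = 1.74e-03, and adjusted p = 0.616 with an estimated correlation). The arsenic list, which holds the deleted gene, had 2 of 5 called lower, ARR1 and ARR2, and 2 adjusted over the list alone (median -0.14, adjusted p = 2.07e-33, and adjusted p = 1.06e-34 with an estimated correlation). The other 10 lists did not pass, with sulfur assimilation, heat shock proteins and the proteasome each at adjusted p = 0.117 (medians -0.09, -0.17 and -0.08). Without arsenite replicate 4 these 3 passed (medians -0.14, -0.28 and -0.14, adjusted p = 0.0304 each), heat shock also without t-BOOH replicate 3 (0.0265) and the proteasome without arsenite replicate 3 (median -0.12, adjusted p = 0.0232). For stress carbohydrates the median (0.08) differed in sign from the mean (-0.05) and the test.

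In all 218 genes were called under arsenite, 46 higher and 172 lower, of which 31 lower genes and no higher gene changed at least 2-fold. The number moved with single arrays, to 40, 29 and 30 without arsenite replicates 1, 2 and 3, to 396 without arsenite replicate 4, and to 371, 122 and 443 without t-BOOH replicates 1, 2 and 3. Leaving out a t-BOOH array did not change the arsenite ratios (median of all genes 0.001304 each time). Those counts moved through the shared estimate of the spread. With the 4 arsenite arrays alone 732 genes were called, 49.7% of them higher against 21.1% with all arrays.

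Under t-BOOH, HSP26, HSP78, GPM1 and RPN13 were among the genes higher in the deletion strain, and INO1, MCH4 and STE2 among those lower. HSP26, a small heat shock protein, had a log2 ratio of 1.90 (SE 0.44) and HSP78, a mitochondrial chaperone, 1.79 (SE 0.37), with replicate 3 at -0.36 and -0.24 against 1.65 or more on the other arrays. The HSP26 call was lost without t-BOOH replicate 2 or 4, the HSP78 call without replicate 4, with values of at least 1.44 and 1.41. GPM1, a glycolytic phosphoglycerate mutase, stood at 1.40 (SE 0.24), THI80 at 1.04 (SE 0.20), MAM33 at 1.02 (SE 0.12), TYE7, a regulator of glycolytic genes, at 0.99 (SE 0.13), KLLA0F20988g at 0.95, SVF1 at 0.93, KLLA0E23497g at 0.93, MDH2 at 0.91 and the proteasome subunit RPN13 at 0.60 (SE 0.08). KLLA0F08371g (1.44) was lost without t-BOOH replicate 1 or 2 (at least 0.92), URA1 (0.94) without replicate 2 (at least 0.69), and UBP6 (0.69) and RPE1 (0.52) without replicate 1, 2 or 4 (at least 0.57 and 0.37). ATP4 (0.43) was lost without replicate 2 or 4 (at least 0.34), and GLC3 (0.30) without any array other than untreated replicates 1 and 2 and arsenite replicate 3 (at least 0.27).

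The lowest genes under t-BOOH were 7 of the chromosome-end genes, from KLLA0C00132g (-2.38, SE 0.19), KLLA0D20009g, KLLA0A00132g, KLLA0E00133g, KLLA0F00154g and KLLA0D00143g to KLLA0B00143g (-2.32, SE 0.21), then INO1, inositol phosphate synthase (-2.28, SE 0.10, limma adjusted p = 7.18e-08), and MCH4 (-2.08, SE 0.23). STE2, the receptor of the alpha-factor pheromone, had a ratio of -1.08 (SE 0.12), AGA2, a mating adhesin, -1.23 (SE 0.22), JLP1 -1.01 (SE 0.18), RSB1 -0.97 (SE 0.16), PDR12 -0.85 (SE 0.13), MET1 -0.81 (SE 0.16), CYB2 -0.81 (SE 0.13), LYS2 -0.80 (SE 0.13) and TRP1 -0.61 (SE 0.11). RPL3 (-1.41, SE 0.30) was lost without t-BOOH replicate 2 (no nearer to 0 than -1.05). SOD1 (-0.84), FRE3 (-0.54) and POS5 (-0.44) were lost without replicate 1, 2 or 4 (no nearer to 0 than -0.62, -0.43 and -0.27), and LEU1 (-0.53) without replicate 2 or 4 (-0.42). CTA1 (-0.58) was lost without untreated replicate 2, arsenite replicate 3 or 4 or t-BOOH replicate 2, 3 or 4 (-0.50), and RPL21A (-0.82) without untreated replicate 1 or 2, arsenite replicate 1, 2 or 4 or t-BOOH replicate 1, 2 or 4 (-0.43).

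Of 27 heat shock genes 13 were higher in the deletion strain under t-BOOH, or 16 adjusted over the list alone, and all 27 were above 0 (median 0.54, adjusted p = 1.20e-07, and adjusted p = 0.164 with an estimated correlation). Of 42 proteasome genes 10 were higher, or 18 adjusted over the list alone (median 0.25, adjusted p = 2.97e-06, and adjusted p = 0.368 with an estimated correlation). Ribosomal protein genes had a median of -0.47, with 6 of 56 called lower, or 3 adjusted over the list alone (adjusted p = 6.77e-06, and adjusted p = 0.672 with an estimated correlation). Without t-BOOH replicate 1 that median was -0.16 (adjusted p = 0.136). Multidrug efflux genes had 4 of 9 called lower, or 7 adjusted over the list alone (median -0.49, adjusted p = 2.67e-04, and adjusted p = 0.134 with an estimated correlation). Mating genes had 7 of 22 lower and 1 higher, or 8 and 1 adjusted over the list alone (median -0.22, adjusted p = 5.62e-03, and adjusted p = 0.134 with an estimated correlation). The arsenic list, which holds the deleted gene, had 2 of 5 called lower, ARR1 and ARR2, and 2 adjusted over the list alone (median -0.36, adjusted p = 8.54e-08, and adjusted p = 4.28e-08 with an estimated correlation). Sulfur assimilation had 6 of 31 lower, or 8 lower and 1 higher adjusted over the list alone (median -0.29, adjusted p = 9.73e-03, and adjusted p = 0.337 with an estimated correlation). Strain markers, led by LYS2 and TRP1, had 2 of 7 lower and 2 adjusted over the list alone (median -0.24, adjusted p = 0.0184, and adjusted p = 0.134 with an estimated correlation). Both calls were lost without t-BOOH replicate 3 (adjusted p = 0.118 and 0.127). Ribosome biogenesis had 0 of 92 called and 0 adjusted over the list alone (median 0.15, adjusted p = 0.0101, and adjusted p = 0.815 with an estimated correlation), lost without t-BOOH replicate 1 (0.469) or 2 (0.0516). The thiol redox, pentose phosphate, iron, stress carbohydrate and mitochondrial lists did not pass. Without t-BOOH replicate 3 thiol redox (median -0.29 in place of -0.15, adjusted p = 0.0274) and mitochondrial respiration (0.17 in place of 0.11, adjusted p = 0.0326) did. For iron uptake the median (0.05) differed in sign from the mean (-0.04) and the test, and for stress carbohydrates the median (-0.04) did so from the mean (0.03) and the test.

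**Figure D2:**
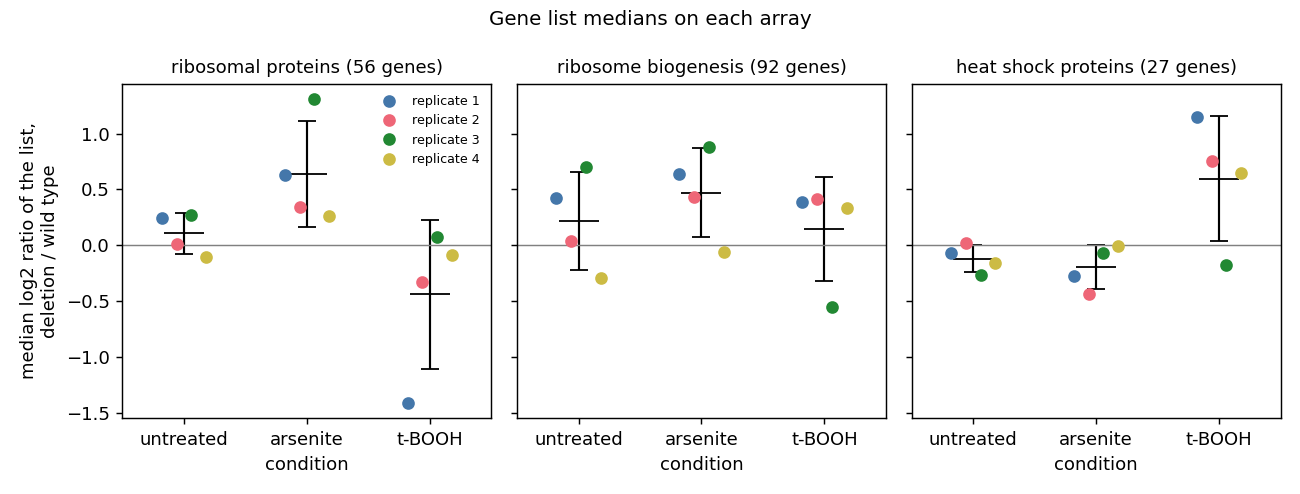
Median log2 ratio of deletion over wild type for ribosomal protein, ribosome biogenesis and heat shock genes on each array, by condition. Coloured points are arrays, the black dash is the mean of 4 and the bar its SD. Heat shock medians under t-BOOH lie at 0.65 to 1.15 except on replicate 3 (-0.18), and the ribosomal protein median of t-BOOH replicate 1 (-1.42) lies below those of the other arrays.

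In all 914 genes were called under t-BOOH, 376 higher and 538 lower, 69 of them by at least 2-fold. The count was 425, 257 and 375 without t-BOOH replicates 1, 2 and 4 and 1570 without replicate 3. With the 4 t-BOOH arrays alone 5 genes were called, all 5 lower, so that no higher call was left, those of the heat shock and proteasome genes included (1257 genes at unadjusted p under 0.05, limma). The residual spread of the ratios, as a root mean square, was 0.297 under t-BOOH, 0.262 in untreated cells and 0.198 under arsenite. The fit shares 1 estimate of the spread, on average too small for t-BOOH and too large for arsenite. The counts of 914 under t-BOOH and 218 under arsenite therefore do not rank the effect of the deletion by condition. Fits on 4 arrays alone estimate the spread with fewer degrees of freedom.

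Genes lower in the deletion strain were shared between conditions, and with all arrays untreated cells had no higher gene to share. The counts take the 12 chromosome-end genes as separate, and all conditions share 1 estimate of the spread. Of the genes lower in untreated cells, 26 were also lower under arsenite, against 1.05 for independent lists, and 25 under t-BOOH, against 3.29. Arsenite and t-BOOH shared 42 lower genes, against 18.3, and 5 higher genes, against 3.41 (Fisher's exact test, one-sided, p = 0.253). Lower in all 3 conditions were 23 genes. They were the 12 chromosome-end genes, ARR1, ARR2, INO1, and 8 genes outside the naming rule that were chosen after their values were seen. Those 8 were BIO2, biotin synthase (-1.004, -1.11 and -0.97 in untreated, arsenite and t-BOOH), ICS2 (-1.50, -0.90 and -1.14), PHO92, KLLA0C00671g, KLLA0D15400g, KLLA0D18964g, KLLA0D19921g and KLLA0F24486g.

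Whether the effect of the deletion differed between conditions was tested directly. Between arsenite and untreated cells 2 genes passed, ARR2 with a difference of -2.75 (SE 0.16, limma adjusted p = 2.64e-06) and JLP1 with -1.92 (SE 0.25, limma adjusted p = 9.52e-03). Both were lower in the deletion strain under arsenite, and JLP1 stood at 0.03 (SE 0.18, n = 4) in untreated cells. The JLP1 call was lost without untreated replicate 1 or 3 or arsenite replicate 1 or 3, which left 1 gene, with a difference of -1.68 or stronger. Without arsenite replicate 4 the count was 9, and without t-BOOH replicate 1 it was 4. With the replicate number as a block the count was 1, and without a dye coefficient 4. All arrays of this comparison lay on slide 1, and the fit on those alone also called 2 genes. The ARR1 ratio did not pass (-0.96, SE 0.17, limma adjusted p = 0.0963). An unadjusted p under 0.05 was reached by 485 genes. Ribosomal protein genes had a median difference of 0.52 with 0 of 56 called and 0 adjusted over the list alone (adjusted p = 1.13e-15, and adjusted p = 0.614 with an estimated correlation). Arsenic detoxification (median -0.37, adjusted p = 1.29e-13, and adjusted p = 7.87e-14 with an estimated correlation) had 1 member called, ARR2, or 2 adjusted over the list alone, and it holds the deleted gene. Ribosome biogenesis (0.25, adjusted p = 3.89e-05, and adjusted p = 0.981 with an estimated correlation), mitochondrial respiration (0.22, adjusted p = 5.86e-03, and adjusted p = 0.614 with an estimated correlation) and thiol redox (-0.12, adjusted p = 0.0148, and adjusted p = 0.796 with an estimated correlation) also passed. Those 3 had 0 members called, and adjusted over the list alone 0, 0 and 2. The ribosome biogenesis and mitochondrial calls were lost without untreated replicate 4 (medians 0.01 and 0.18, adjusted p = 0.918 and 0.0894), and that of thiol redox without untreated replicate 1 (0.0573) or 2 (0.155). The other 9 lists did not pass, except the proteasome without untreated replicate 3 (median -0.14 in place of -0.01, adjusted p = 0.0165). The medians of multidrug efflux (-0.01), mating (0.01) and strain markers (-0.01) differed in sign from their means (0.01, -0.08 and 0.00) and tests.

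Between t-BOOH and untreated cells the deletion effect differed for 144 genes, 48 with a higher and 96 with a lower ratio under t-BOOH. The highest were KLLA0E23497g (1.33, SE 0.25), THI80 (1.19), DPB3 (1.12), MAM33 (1.11, SE 0.17) and the replication gene MCM3 (1.07), and the lowest MCH4 (-1.76, SE 0.33), GUT2 (-1.74), KLLA0B07139g (-1.55), GDS1 (-1.48) and SPL2 (-1.34). These calls were not stable to single arrays. THI80, DPB3, GUT2, KLLA0B07139g and GDS1 were lost on leaving out any array other than t-BOOH replicate 3, and all 10 without untreated replicate 1 or t-BOOH replicate 2. KLLA0E23497g, MCM3, MCH4 and SPL2 were also lost without t-BOOH replicate 1 or 4, KLLA0E23497g and SPL2 without untreated replicate 3, and MCH4 and SPL2 without untreated replicate 2 or 4. The values stayed at 0.96 or more for the higher and -1.09 or lower for the lower genes. The count was 3, 43, 35 and 63 without untreated replicates 1 to 4, 53, 49, 79 and 80 without arsenite replicates 1 to 4, and 17, 1 and 6 without t-BOOH replicates 1, 2 and 4. Without t-BOOH replicate 3 it was 1076. On the 8 arrays compared alone it was 3. Slide and condition cannot be told apart here. The ARR1 difference did not pass (-0.55, SE 0.17, limma adjusted p = 0.0838). Among lists, heat shock (median 0.68, 3 called higher, or 11 adjusted over the list alone; adjusted p = 6.12e-09, and adjusted p = 0.345 with an estimated correlation) and the proteasome (0.33, 2 higher, or 13 adjusted over the list alone; adjusted p = 6.12e-09, and adjusted p = 0.345 with an estimated correlation) shifted up. Ribosomal proteins (-0.59, 0 called and 0 adjusted over the list alone; adjusted p = 6.86e-08, and adjusted p = 0.536 with an estimated correlation) and multidrug efflux (-0.46, 2 lower, or 3 adjusted over the list alone; adjusted p = 4.52e-03, and adjusted p = 0.345 with an estimated correlation) shifted down. Mitochondrial respiration (0.17, 0 called and 0 adjusted over the list alone; adjusted p = 0.0350, and adjusted p = 0.408 with an estimated correlation) lost its call without untreated replicate 3 (0.0561) or 4 (0.111) or t-BOOH replicate 1 (0.264). The other 9 lists did not pass. Mating (median -0.20, adjusted p = 0.0556) passed without untreated replicate 1 (0.0465), 2 (0.0487) or 4 (0.0466) or t-BOOH replicate 3 (median -0.35, adjusted p = 0.0362). Ribosome biogenesis (-0.06, adjusted p = 0.922) passed without untreated replicate 4 (-0.28, adjusted p = 6.89e-04), and with the other sign without untreated replicate 3 (0.16, adjusted p = 0.0225) or t-BOOH replicate 3 (0.13, adjusted p = 0.0362). The medians of pentose phosphate (-0.29) and sulfur assimilation (0.08) differed in sign from the test, and that of sulfur assimilation also from its mean (-0.02).

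Between arsenite and t-BOOH the deletion effect differed for 406 genes, 230 higher and 176 lower under arsenite. ARR2 (-2.45, SE 0.16, limma adjusted p = 1.03e-05) and KLLA0E23497g (-1.85, SE 0.25) were lower under arsenite, while MCH4 (2.14, SE 0.33) and BIO4 of biotin synthesis (1.76, SE 0.32) were higher. These genes kept their calls on leaving out any array. HSP26 (-2.80), HSP78 (-2.11), KLLA0F08371g (-1.90), RPL3 (1.90) and KLLA0B07139g (1.82) were lost without arsenite replicate 1, 2 or 3 or t-BOOH replicate 2 or 4, and HSP78 also without t-BOOH replicate 1, with values no nearer to 0 than -2.34, -1.73, -1.38, 1.54 and 1.51. ARR1 did not pass (-0.40, SE 0.17, limma adjusted p = 0.155). Ribosomal protein genes showed the widest shift of any list, with 33 of 56 higher under arsenite, or 53 adjusted over the list alone (median 1.14, adjusted p = 9.89e-27, and adjusted p = 0.219 with an estimated correlation). Heat shock genes had 9 of 27 lower, or 17 adjusted over the list alone (median -0.80, adjusted p = 1.66e-09, and adjusted p = 0.219 with an estimated correlation). The proteasome had 3 of 42 lower and 3 adjusted over the list alone (-0.34, adjusted p = 4.17e-08, and adjusted p = 0.349 with an estimated correlation), and multidrug efflux 3 of 9 higher, or 4 adjusted over the list alone (0.53, adjusted p = 3.45e-03, and adjusted p = 0.303 with an estimated correlation). The arsenic list had 1 of 5 lower, ARR2, and 1 adjusted over the list alone (-0.07, adjusted p = 9.46e-04, and adjusted p = 2.85e-03 with an estimated correlation). Ribosome biogenesis had 0 of 92 called and 0 adjusted over the list alone (0.35, adjusted p = 3.29e-03, and adjusted p = 0.818 with an estimated correlation) and lost its call without arsenite replicate 3 (0.0886) or t-BOOH replicate 3 (0.865). The other 8 lists did not pass, except thiol redox without t-BOOH replicate 1 (median -0.29 in place of -0.13, adjusted p = 0.0348). For mitochondrial respiration the median (-0.05) and test differed in sign from the mean (0.01). The count was 44, 56 and 82 without arsenite replicates 1 to 3, 37 and 49 without t-BOOH replicates 2 and 4, and 941 without t-BOOH replicate 3. Slide and condition cannot be told apart.

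In the wild type, arsenite raised genes of arsenic handling, protein folding and the proteasome. KLLA0C18931g rose by 5.97 on the log2 scale (SE 0.34), a 62.8-fold change, HSP26 by 4.30 (SE 0.75), CUZ1, whose yeast counterpart binds Cdc48 and the proteasome, by 3.91 (SE 0.34) and ARR2 by 3.79 (SE 0.20). KLLA0E03763g (3.78), KLLA0C19547g (3.78), KLLA0C14993g (3.62), KLLA0C01562g (3.61), KLLA0F24948g (3.58) and KLLA0D01243g (3.43) completed the 10 highest. SRX1 rose by 3.14 (SE 0.23), CCP1, cytochrome c peroxidase, by 2.62 (SE 0.21), HSP78 by 2.41 (SE 0.49), STE6 by 2.26 (SE 0.33), JLP1 by 2.05 (SE 0.26), HOM3 by 1.63, KAR4 by 1.54 and YCF1, a vacuolar transporter of glutathione conjugates, by 1.47 (SE 0.15). GRX4 (1.32), RSB1 (1.26), PDR1 (1.10), ZWF1, the entry enzyme of the pentose phosphate pathway (0.97), and HIS3 (0.87) also rose. ARR1 rose by 0.57 (SE 0.19, limma adjusted p = 0.0354), a call lost without untreated replicate 1, 2 or 3 or arsenite replicate 1, 2 or 3 (values of 0.53 or more). ALD6 (1.53) was lost without arsenite replicate 2 (at least 1.27), and NPL4 (1.49) without untreated replicate 4 or arsenite replicate 1 or 2 (at least 0.99).

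CTR1 and FRE1 were among the genes that fell with arsenite, while of 23 iron uptake genes 5 rose and 2 fell, or 6 and 3 adjusted over the list alone (median 0.22, adjusted p = 0.517). KLLA0E24861g changed by -4.50 (SE 0.51), DIT2 by -3.22 (SE 0.72), the copper transporter CTR1 by -3.20 (SE 0.47), the metalloreductase FRE1 by -2.98 (SE 0.41), KLLA0E24883g by -2.89 and DTR1 by -2.63. KLLA0D00187g, KLLA0D19965g, KLLA0B00187g and KLLA0C00176g changed by -2.76 to -2.68, ATP20 by -0.73 and URA3 by -0.71. The calls of NOP58 (-1.34), MAK16 (-1.13), XBP1 (-0.999), RPS22B (-1.15) and RPS22A (-1.001) were lost without arsenite replicate 2, and all but XBP1 without arsenite replicate 1. NOP58 was also lost without untreated replicate 1, 2 or 4 or arsenite replicate 3 or 4, MAK16 without untreated replicate 2, XBP1 without untreated replicate 1 or 3, and RPS22B without untreated replicate 4, arsenite replicate 3 or 4 or t-BOOH replicate 2 or 4. Values came no nearer to 0 than -1.06, -0.93, -0.81, -0.63 and -0.57. Of 42 proteasome genes 28 rose, or 35 adjusted over the list alone (median 0.71, adjusted p = 1.68e-13, and adjusted p = 0.0228 with an estimated correlation). Of 27 heat shock genes 18 rose and 1 fell, or 20 and 1 adjusted over the list alone (median 1.28, adjusted p = 7.19e-10, and adjusted p = 0.0228 with an estimated correlation). Of 5 arsenic genes 3 rose, or 3 with 1 lower adjusted over the list alone (median 0.57, adjusted p = 1.23e-06, and adjusted p = 2.88e-06 with an estimated correlation). Of 27 thiol redox genes 11 rose and 1 fell, or 14 and 1 adjusted over the list alone (median 0.62, adjusted p = 2.56e-07, and adjusted p = 0.0591 with an estimated correlation). Sulfur assimilation had 10 of 31 higher and 4 lower, or 11 and 4 adjusted over the list alone (median 0.31, adjusted p = 0.0186, and adjusted p = 0.249 with an estimated correlation). Multidrug efflux had 4 of 9 higher and 4 adjusted over the list alone (0.58, adjusted p = 0.0245, and adjusted p = 0.438 with an estimated correlation), lost without untreated replicate 4 (0.155) or arsenite replicate 4 (0.0564). Ribosome biogenesis had 18 of 92 lower, or 0 adjusted over the list alone (-0.56, adjusted p = 2.88e-06, and adjusted p = 0.493 with an estimated correlation). Ribosomal proteins had 5 of 56 lower, or 0 adjusted over the list alone (-0.68, adjusted p = 2.88e-06, and adjusted p = 0.493 with an estimated correlation). The pentose phosphate, stress carbohydrate, mitochondrial, mating and strain marker lists did not pass. In all 1130 genes were called, 623 higher and 507 lower, 392 by at least 2-fold. All arrays of this comparison lay on slide 1, and the fit on them alone called 1700. The count was 676 and 627 without arsenite replicates 1 and 2, and 1820 without t-BOOH replicate 1.

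**Figure D3:**
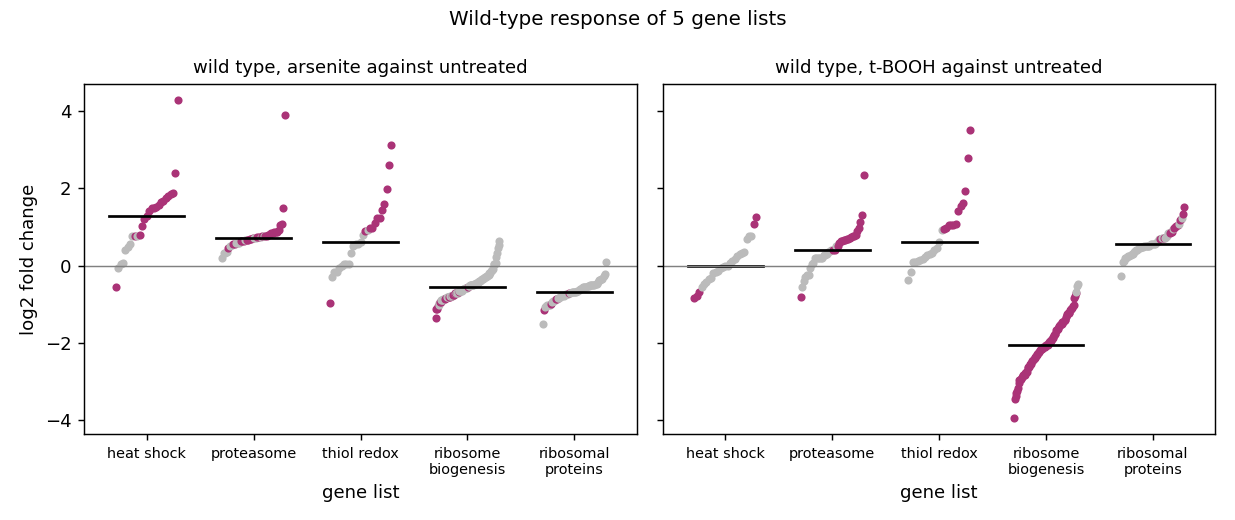
Log2 fold change of each gene of 5 lists in the wild type under arsenite (left) and t-BOOH (right), against untreated cells. Points are genes in rising order, purple where the adjusted p was under 0.05 and grey otherwise, and the black line is the list's median. The medians are 1.28, 0.71, 0.62, -0.56 and -0.68 under arsenite and -0.00, 0.40, 0.60, -2.06 and 0.56 under t-BOOH, from left to right.

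With t-BOOH the wild type lowered ribosome biogenesis genes nearly throughout. Of 92 members 89 fell and none rose, with 92 lower adjusted over the list alone (median -2.06, adjusted p = 3.11e-34, and adjusted p = 0.0461 with an estimated correlation), among them NOP13 (-3.95, SE 0.25) and SOF1 (-3.44, SE 0.31). ALB1, a ribosome assembly factor outside the list, changed by -3.98 (SE 0.36). Other strong decreases were KLLA0E09021g (-4.87, SE 1.17), ATO3 (-4.41, SE 0.42), KLLA0F19371g (-4.26), the G1 cyclin PCL1 (-4.23, SE 0.25), KLLA0C15741g (-4.07), KLLA0F26818g (-4.06), ACS1, acetyl-CoA synthetase (-3.64, SE 0.45), and KLLA0F16489g (-3.48). RME1 (-2.90), MET1 (-2.76, SE 0.27), the siderophore and iron uptake genes FIT2 (-1.96) and FET3 (-1.94), USV1 (-1.69), GPH1 (-1.65), the respiratory genes CYC7 (-1.51) and QCR2 (-1.34), RKI1 (-1.03), ADE1 (-0.99) and POS5 (-0.62) also fell.

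KLLA0C18931g again rose most, by 6.03 (SE 0.34), a 65.5-fold change. The chromosome-end genes KLLA0E00133g (4.79, SE 0.39), KLLA0F00154g, KLLA0D00143g, KLLA0A00132g, KLLA0B00143g and KLLA0D20009g (4.51, SE 0.37) followed with KLLA0C18711g (4.72), KLLA0B00517g (4.71) and KLLA0C00198g (4.38). STE3, the receptor of the a-factor pheromone, rose by 4.19 (SE 0.23), JLP1 by 3.63 (SE 0.26), SRX1 by 3.51 (SE 0.23), CCP1 by 2.80 (SE 0.21), CUZ1 by 2.35 (SE 0.34), RSB1 by 2.23 (SE 0.21), ARR2 by 1.91 (SE 0.20), TRP1 by 1.86, TPO1 by 1.61, YCF1 by 1.52 (SE 0.15), UFD1 by 1.31, AHA1 by 1.27, APJ1 by 1.09 and ARR1 by 0.61 (SE 0.19, limma adjusted p = 0.0112). RPS0A (1.53) and RPS11B (1.33) also rose. Of 27 thiol redox genes 12 rose, or 11 adjusted over the list alone (median 0.60, adjusted p = 3.03e-03, and adjusted p = 0.427 with an estimated correlation). Of 5 arsenic genes 4 rose and 4 adjusted over the list alone (median 1.33, adjusted p = 0.0137, and adjusted p = 0.0338 with an estimated correlation). Of 42 proteasome genes 20 rose and 1 fell, likewise 20 and 1 adjusted over the list alone (median 0.40, adjusted p = 0.0436, and adjusted p = 0.682 with an estimated correlation). That call was lost without untreated replicate 2 (0.0750) or 4 (0.102), arsenite replicate 2 (0.0504), or t-BOOH replicate 2 (0.0615) or 3 (0.0712). Heat shock genes did not pass (2 of 27 higher and 3 lower, or 2 and 1 adjusted over the list alone; median -0.00, and mean 0.04 of the other sign). Ribosomal proteins (13 of 56 higher, or 7 adjusted over the list alone; median 0.56, adjusted p = 0.0504), mitochondrial respiration (median -0.43, adjusted p = 0.0504) and multidrug efflux (0.70, adjusted p = 0.0572) did not pass. Ribosomal proteins passed without untreated replicate 4 (median 0.90, adjusted p = 2.26e-04), arsenite replicate 1 (0.0488) or 3 (0.0406), or t-BOOH replicate 3 (0.0158) or 4 (0.0446). Mitochondrial respiration passed without arsenite replicate 1 (0.0488) or t-BOOH replicate 1 (0.0487) or 3 (0.0158), and multidrug efflux without untreated replicate 3 (0.0473) or t-BOOH replicate 3 (0.0130). Stress carbohydrates (median -0.42, adjusted p = 0.346) passed without untreated replicate 4 (-0.56, adjusted p = 0.0102). The pentose phosphate, sulfur, iron, mating and strain marker lists did not pass. In all 2484 genes were called, 1374 higher and 1110 lower, 1152 by at least 2-fold. Slide and condition cannot be told apart for these arrays, and median scaling moved the median of all genes to 0.15.

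The stress responses of the strains were set against each other. For arsenite 1130 genes were called in the wild type and 524 in the deletion strain, and for t-BOOH 2484 and 2181. Of the wild-type calls 1126 and 2425 had the same sign in the deletion strain. The correlation of the 2 responses over genes was 0.909 for arsenite and 0.930 for t-BOOH. Both strains shared each array, so their responses are not independent. A difference between the strains was called for 2 of the 1130 and 97 of the 2484 genes. ARR2 rose by 3.79 with arsenite in the wild type and by 1.04 in the deletion strain. Arsenite and t-BOOH raised 337 genes in common in the wild type, against 168.9 for independent lists, and lowered 200, against 111. Both responses use the same untreated arrays. Unchanged groups against those arrays gave a correlation of 0.499 over genes in 50 simulations, where the observed correlation was 0.384. The covariance was 0.234 observed and 0.0320 simulated. The simulations held no changed genes and called 0 as higher and 0 as lower in both. With the untreated arrays split between the responses, 190 or 184 genes were higher in both and 176 or 94 lower. The numbers for independent lists, 168.9 and 111, belong to the fit of all arrays. None were computed for the split fits, so these counts cannot be set against them.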

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

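The tests of cross-hybridisation and of t-BOOH replicate 3 were chosen after the result was seen. The fit without 3 arrays, named with the processing below, was chosen then too.

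Single arrays far from the other 3 of their condition stood out in 40 of 281 groups of 4 values, where chance gives about 1 in 20 groups, or 14.05. The groups are not independent, since all come from the same 12 arrays and 1 array can shift many genes together. Most are also genes picked for their change. Setting 40 against 14.05 is therefore no test. Among log2 ratios of deletion over wild type these were KLLA0E00573g on arsenite replicate 3 (1.51), STE6 on arsenite replicate 4 (-0.61), and on t-BOOH replicate 3 THI80 (0.003171), KLLA0E00133g (-1.44), KLLA0F00154g (-1.36), KLLA0D00143g (-1.40) and KLLA0B00143g (-1.27). Among wild-type log2 levels, untreated replicate 4 stood apart for HSP26 (7.94), KLLA0E24861g (14.23), DIT2 (9.40), CTR1 (14.00), KLLA0E24883g (10.96), NPL4 (10.36), RPS22B (14.67), RPS22A (15.93), FIT2 (14.25), USV1 (9.46), GPH1 (12.71), RME1 (7.51), RPS0A (15.82) and RPS11B (15.94). Other untreated values were ATO3 on replicate 2 (14.92) and TPO1 on replicate 3 (15.19). Arsenite replicate 4 stood apart for KLLA0C19547g (11.64), KLLA0F24948g (13.66), CTR1 (11.99) and FRE1 (8.21), and arsenite replicate 3 for KLLA0E24883g (9.82). T-BOOH replicate 3 did so for KLLA0B00517g (11.74), CYC7 (13.20), QCR2 (13.85) and RSB1 (14.23), and t-BOOH replicate 1 for ATO3 (9.265) and KLLA0F26818g (9.24). Among whole-array values these were the genes above background in Cy3 on arsenite replicate 3 (98.5%) and in Cy5 on untreated replicate 4 (99.0%), and the mean correlation of ratios on arsenite replicate 4 (0.444). For levels the mean correlation stood apart on untreated replicate 4 (0.943), arsenite replicate 3 (0.994) and t-BOOH replicate 1 (0.916).

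The effect of the deletion differed between conditions, by a test of the difference itself, in 37 results. Of the lists among them, every list but arsenic detoxification lost its call with an estimated correlation between genes. For arsenic detoxification, which holds the deleted gene, that estimate was 0, under the preset 0.01. Keeping its call in both of its differences was therefore no stricter test. Between arsenite and untreated cells the results were ARR2 (-2.75) and JLP1 (-1.92), and the medians of arsenic detoxification (-0.37), thiol redox (-0.12), ribosome biogenesis (0.25), mitochondrial respiration (0.22) and ribosomal proteins (0.52). The last 4 were at adjusted p = 0.796, 0.981, 0.614 and 0.614 with an estimated correlation. Between t-BOOH and untreated cells they were KLLA0E23497g (1.33), THI80 (1.19), DPB3 (1.12), MAM33 (1.11), MCM3 (1.07), MCH4 (-1.76), GUT2 (-1.74), KLLA0B07139g (-1.55), GDS1 (-1.48) and SPL2 (-1.34), with heat shock (0.68), proteasome (0.33), mitochondrial respiration (0.17), multidrug efflux (-0.46) and ribosomal proteins (-0.59). With an estimated correlation these 5 lists were at adjusted p = 0.345, 0.345, 0.408, 0.345 and 0.536, and chance was not excluded for the count of genes, with 3 of 35 splits as large. Between arsenite and t-BOOH they were MCH4 (2.14), RPL3 (1.90), KLLA0B07139g (1.82), BIO4 (1.76), HSP26 (-2.795), ARR2 (-2.45), HSP78 (-2.11), KLLA0F08371g (-1.90) and KLLA0E23497g (-1.85). The lists there were arsenic detoxification (-0.07094), heat shock (-0.80), proteasome (-0.34), ribosome biogenesis (0.35), multidrug efflux (0.53) and ribosomal proteins (1.14). The last 5 were at adjusted p = 0.219, 0.349, 0.818, 0.303 and 0.219 with an estimated correlation.

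The 12 genes at chromosome ends were lower in the deletion strain in all 3 conditions. A lowering shared by the outermost 10 genes of each chromosome end is argued against. The other 102 genes there had a median untreated log2 ratio of -0.01638 (95% interval -0.08 to 0.03). Each of the 12 was gene 1 or 2 from its end, while the 102 reached further in. An effect of position confined to the very ends therefore stays open. An effect of the deletion on its neighbourhood as a whole is argued against, since 13 neighbours of ARR1 had a median of 0.07181 (-0.05 to 0.12). ARR2 (-1.65 in untreated cells) and the paired chromosome-end genes were left out of those neighbours. An effect confined to the genes left out stays open. Cross-hybridisation between copies, known as such only by like coding length since sequences were not compared here, stays open. The SD over copies within an array was at most 0.09998 of the SD over arrays, so the 12 may stand for fewer changed loci. A difference between the strains at these ends other than the deletion, and an effect of the deleted factor, were not tested.

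Ribosomal protein genes were higher in the deletion strain under arsenite and lower under t-BOOH, where the array medians were -1.415, -0.33, 0.07 and -0.09 and the call was lost without replicate 1 (median -0.16, adjusted p = 0.136). The 293 genes of like brightness had a median arsenite log2 ratio of -0.02369 (95% interval -0.07 to 0.01). Loess had already centred the ratios at each brightness, so that median lay near 0 largely by construction. It cannot decide on an intensity bias, and the matched genes were not examined without loess. The loess step as the cause is argued against by a difference between conditions of 0.94 with median centring against 1.14. A single array as the cause stays open, since without t-BOOH replicate 1 the difference was 0.80, between the bounds set for the test. The slide cannot be told apart from t-BOOH. Whether the deletion itself shifts these genes remains a hypothesis, and with an estimated correlation between genes the list did not pass.

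T-BOOH replicate 3 differed from the other t-BOOH arrays. Exchanged dye labels are argued against, since with the sign turned its highest correlation with another t-BOOH array was -0.008367. RNA of the same strain in both channels is argued against by ARR1 and ARR2, the higher of which stood at -1.56, and low signal by a median Cy3 signal of 1168.75, within the range of the other t-BOOH arrays. A difference in the cultures or in the exposure was not tested.

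Other groupings of the arrays were counted for each comparison. With the signs of the 4 ratios flipped there are 8 groupings, too few for a share under 0.05. In 1 of the 8, the real one, 31 genes were called in untreated cells (highest other 4), 218 under arsenite (0) and 914 under t-BOOH (789, with the sign of replicate 3 turned). Of the 35 splits of 8 arrays, 1, the real one, gave as many genes for arsenite against t-BOOH ratios (406, highest other 44), and for the wild-type responses to arsenite (1130, highest other 14) and t-BOOH (2484, highest other 678). The real count thus exceeded that of every other split there. That is the smallest share 35 splits can give, and it was not corrected for the number of comparisons. By itself it does not exclude chance. For arsenite against untreated ratios the real split was also the only 1 of the 35 to give as many, but with 2 genes against a highest other of 1. Without untreated replicate 1 or 3 or arsenite replicate 1 or 3 the real count was 1 too. For arsenite against t-BOOH ratios the real count was 44 without arsenite replicate 1 and 37 without t-BOOH replicate 2, no more than the highest other split of all 8 arrays. Splits with an array left out were not run, so these counts have no split of the same size beside them. For t-BOOH against untreated ratios 3 of the 35 splits gave as many as the real 144, the highest other 255, and chance cannot be excluded.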

How the results depend on the processing

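The fit without untreated replicate 4 and t-BOOH replicates 1 and 3, which stood apart from their groups, was chosen after seeing the data. Of 199 named calls 125 were kept in every alternative other than that fit and the omissions of single arrays, and 143 on leaving out each array in turn. Of 45 list calls 38 and 32 were kept, the estimated correlation aside. That correlation left 10 of the 45 list calls. Those of the arsenic list were among them, where the estimate was 0 and so no stricter than the preset. On the arrays of the conditions compared alone, 732 genes were called for the deletion under arsenite (218 with all arrays), 5 under t-BOOH (914), 3 for the difference of t-BOOH from untreated (144), 164 for that of arsenite from t-BOOH (406) and 1700 for the wild-type arsenite response (1130). Without a dye coefficient the difference of arsenite from untreated was called for 4 genes (2). With the replicate number as a block it was called for 1 gene, and that of t-BOOH from untreated for 17. Whether the numbers pair the arrays is not settled. Residual correlations of the ratios between arrays of like number ran from -0.316 to 0.348, with 6 of 12 above 0.1. Arrays of unlike number were not compared as a baseline, so the block is given as a check. Without the 3 arrays, 72 genes were called in untreated cells (31), 15 of them higher, 824 under arsenite, 695 for t-BOOH from untreated, 962 for arsenite from t-BOOH and 2375 for the wild-type arsenite response. None of the 3 was an arsenite array, and the median arsenite ratio of all genes was 0.001304 with and without them. The arsenite count of the deletion thus moved through the shared estimate of the spread, not through the ratios. The cause of the other changes was not tested.

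Leaving out 1 array gave 19 to 51 genes for the deletion in untreated cells, 29 to 443 under arsenite and 257 to 1570 under t-BOOH, 1 to 9, 1 to 1076 and 37 to 941 for arsenite from untreated, t-BOOH from untreated and arsenite from t-BOOH, and 627 to 1820 and 2128 to 2824 for the wild-type responses to arsenite and t-BOOH. List calls ranged from 42 to 50. The proteasome median in untreated cells ranged from -0.147 to 0.01269 and changed sign without untreated replicate 3. The ribosome biogenesis median for t-BOOH from untreated ranged from -0.28 to 0.16, with 0.1568 without untreated replicate 3 and 0.1264 without t-BOOH replicate 3 in place of -0.06, and the cause was not tested. The counts stayed within 1.5 times under no background subtraction, processed signals, median centring, the filters, the trended robust variance, the authors' log2 table, wild-type channels alone and median scaling. Median scaling moved the median of all genes in the wild-type t-BOOH response from 0.08 to 0.15, so changes there are relative to that. The brightest probe was not run, with 1 probe per gene, nor was a slide block, with each condition on 1 slide. Signal over background limited little, with at least 97.4% of genes well above background in each channel.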

Other observations

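The 12 chromosome-end genes come in sets of like coding length, 5 of 1047 and 7 of 1524 bases. They were grouped after their values were seen. In the wild type both sets rose with t-BOOH, the first by 3.58 (KLLA0A00110g) to 3.83 (KLLA0E00111g) and the second by 4.37 (KLLA0C00132g) to 4.79 (KLLA0E00133g) on the log2 scale. The deletion ratio of the first set was -2.31 to -2.34 in untreated cells and -1.40 to -1.43 under t-BOOH, that of the second -2.03 to -2.23 and -2.32 to -2.38.

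Of 22 mating genes 8 rose in the wild type with t-BOOH and 4 fell, RME1 (-2.90) among them. STE2 (1.31, SE 0.23) and AGA2 (1.25, SE 0.34), picked from the list after their values were seen, rose, and both were lower in the deletion strain under t-BOOH. The list as a whole did not pass (adjusted p = 0.226).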
